A study of Mus musculus with 8 samples.

How the data were processed

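ATAC-seq libraries were made from 50000 sorted cells each by Tn5 tagmentation of nuclei and a Nextera library preparation, per the labels' protocols. The labels give 8 libraries, 4 control and 4 Carm1-KO, as biological replicates. The submitters' processing notes name Trim Galore 0.6.10, cutadapt 4.5, Bowtie2 2.5.2 and the mm10 build. The peak caller, its settings, any shift of reads for the transposase, duplicate removal and the way the 4 libraries of a group were combined are not given in the sources used here. A list called on combined libraries does not show whether a peak was present in 1 library or in all 4.

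The deposited peak lists are in narrowPeak layout. The authors' fold enrichment of each peak is a ratio over the caller's background. The authors also give a −log10 p-value, which was not used, and a −log10 q-value of each peak, and the lowest deposited −log10 q-value was 1.31 in the control list and 1.30 in the Carm1-KO list. The deposited score column follows the −log10 q column and was not used further. The other deposited columns hold positions and the summit's distance from the peak's start, in bp. These values are the authors' own and were used to describe, rank or filter peaks within their list. Numbers of peaks past a −log10 q threshold were compared between the lists, but the fold of a peak in one list was not tested against that in the other. Replicates could not be compared, and depth per library is unknown.

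The 2 deposited region lists name each region by its number in a merged set. Merging the peaks of both lists with a fold of at least 10 gave a set in which all 3127 Carm1-KO-specific and all 218 control-specific regions matched by number and by position, as 190 bp around the middle of a merged peak. This set, 89282 regions on chromosomes 1 to 19 and X, served as background. Peaks on Y (21 control, 23 Carm1-KO) were left out.

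Peaks were compared by overlap of at least 1 bp. Each region was assigned to the nearest protein-coding gene of the GRCm38.p6 gene table, by distance to the gene span, up to 100 kb. The table gives no strand, so transcription start sites were not known, and the planned promoter share was replaced by the share within 1 kb of either gene end. Exons, introns and untranslated regions were likewise not known. No genome sequence was used, so the 30 planned motifs were not tested. Of 495 list entries, 487 matched a gene by symbol and 3 by synonym, and 5 did not match. They stand for 462 distinct genes.

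The 20 gene lists, written before the data were examined, cover the functions of cDC1s, CARM1 substrates, metabolism, the cell cycle and 8 other cell types. Each was tested by a one-sided permutation test with 100000 random gene sets matched on the number of merged regions per gene, over the 16380 genes with a merged region, with Benjamini-Hochberg adjustment over the lists at 0.05. Gene ends and chromosomes were tested by two-sided Fisher's exact tests. Intervals are exact at 95% and cover counting error only. Genes were named by a rule fixed in advance: the 15 genes with the most Carm1-KO-specific regions and the 10 with the most control-specific regions (ties by the total length of those regions, which did not separate regions of equal width, then by symbol), up to 4 members of each list with the region nearest to a gene end (planned for the start site), Carm1, and the 5 regions per group with the highest fold in their own list.

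The methods were tested on simulated data. The overlap count matched bedtools (6268 of 30000 intervals by both). For the Carm1-KO-specific regions, with 50 repeats over 16380 genes, a maturation list drawn at 4 times the rate of other regions was called in 96% of repeats and one drawn at 2 times in 22%, and at an unchanged rate in 0%. For the control-specific regions, 4 times gave a call in 16%. A planted gene-end odds ratio of 0.2 came back as 0.200 for Carm1-KO-specific and 0.212 for control-specific regions. The binomial test per gene called on average 0 genes with nothing planted and 26.7% of genes planted at 10 times. The simulated regions were drawn without clustering and planted only in genes with at least 10 merged regions. The simulation therefore does not cover clustered regions or planted genes with fewer merged regions. Alternatives were the overlap rule, stricter thresholds, the gene distance, the background and the matching. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.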

Results

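The series profiled open chromatin by ATAC-seq in type 1 conventional dendritic cells (cDC1s), the dendritic cells best known for presenting antigen taken up from other cells to CD8 T cells. The cells were grown from mouse bone marrow and sorted, and 50000 cells entered each library. The labels give 4 control libraries and 4 libraries that lack Carm1, the gene of an arginine methyltransferase that acts on histones and on coactivators. The question was how the loss of this enzyme alters accessible chromatin in cDC1s. The files analysed hold 1 peak list per group and 1 list of regions that the authors assigned to each group, with no values per library. The spread between the 4 libraries of a group is therefore unknown, and no p-value below tests a difference between the groups of libraries. Read depth is unknown too. The control list held 246945 peaks on chromosomes 1 to 19 and X and the Carm1-KO list 248915, with median widths of 149 and 146 bp. They covered 48.0 and 47.2 Mb. Coordinates are those of the mm10 build, counted from 1.

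Carm1 itself lies on chromosome 9 from 21546894 to 21589467. Each list held 6 peaks in the gene and the 1 kb on either side. Of these, 4 control peaks and 5 Carm1-KO peaks overlapped a peak of the other list. The strongest control peak spanned 21546110 to 21547391 and had an authors' fold enrichment of 15.1, and the strongest Carm1-KO peak spanned 21546110 to 21546968 with 15.5. Both covered the lower gene end at 21546894. No region specific to either group was assigned to Carm1. Because the deleted part of the gene is not given in the sources used here, these peaks do not check the labels.

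Most peaks were common to both groups, and the strong peaks that were not common were nearly all on the Carm1-KO side. A Carm1-KO peak overlapped 81.9% of the control peaks (202214 peaks, exact binomial 95% interval 81.7 to 82.0), and a control peak overlapped 82.1% of the Carm1-KO peaks (204357 peaks, 81.9 to 82.2). Among peaks with a −log10 q of at least 50, a threshold chosen after the data were seen, 2605 of 83151 Carm1-KO peaks had no overlapping control peak, against 16 of 87454 control peaks with no overlapping Carm1-KO peak. These shares were 3.13% and 0.0183%. The 2605 peaks were spread over 20 chromosomes, and 65.2% of them overlapped a region that the authors listed as Carm1-KO-specific. Weak peaks showed the opposite order, since below a −log10 q of 5 the share without a counterpart was 62.9% in the control list and 55.3% in the Carm1-KO list. The absence of a peak means that none passed the authors' threshold, not that the site was closed.

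**Figure D1:**
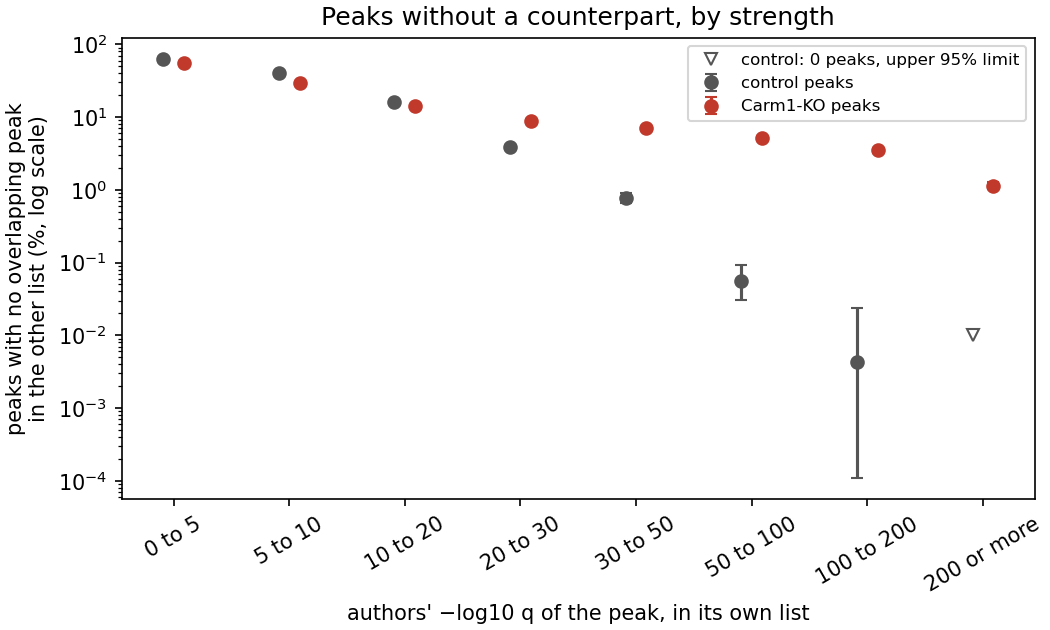
Percent of peaks (log axis) with no overlapping peak in the other list, by the authors' −log10 q of the peak in its own list, with exact 95% binomial intervals that cover counting error only; the open triangle is the upper limit for a count of 0. In the bin from 100 to 200 the share was 3.48% of Carm1-KO peaks and 0.00425% of control peaks.

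The authors listed 3127 Carm1-KO-specific and 218 control-specific regions on these chromosomes, each 190 bp wide. They were 3.50% and 0.244% of the 89282 regions in the merged set they were drawn from. Of the Carm1-KO-specific regions, Slc7a11, the cystine and glutamate exchanger gene, had the most, 9 of its 29 merged regions. Il1rn, the antagonist of the interleukin 1 receptor, had 5 of 9, and Slco5a1, a transporter gene transcribed in migratory dendritic cells, had 6 of 15. Of the 3127 regions, 1863 (59.6%, exact 95% interval 57.8 to 61.3) overlapped no control peak, and the other 1264 overlapped a control peak with a median fold of 4.74 in the control list. Of the 218 control-specific regions, 1 overlapped no Carm1-KO peak, and the other 217 overlapped one with a median fold of 6.27 in the Carm1-KO list. In the whole merged set, 2430 regions overlapped a Carm1-KO peak and no control peak, and 1863 of these were listed as Carm1-KO-specific. Only 44 overlapped a control peak and no Carm1-KO peak, and 1 of these was listed as control-specific. The rule by which the authors called a region specific is not given in the sources used here.

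**Figure D2:**
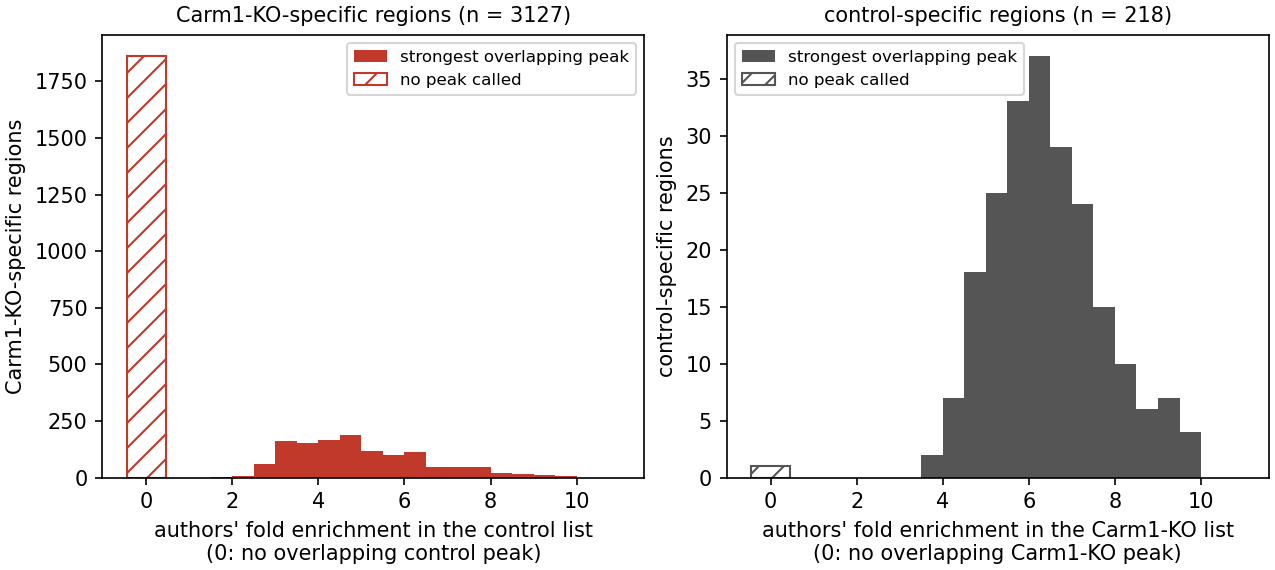
Number of group-specific regions by the authors' fold enrichment of the strongest overlapping peak in the other group's list, with hatched bars for regions that overlap no such peak. The hatched bars hold 1863 of 3127 Carm1-KO-specific and 1 of 218 control-specific regions.

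Among the 15 genes with the most Carm1-KO-specific regions, Slc7a11 was followed by Atxn1, Pakap and the transcription factor gene Runx2 with 8 each and by the DNA repair gene Rad51b with 7. Arnt2, Eea1 (an early endosome tether), Phlpp1, Ptpn14, Ralgapa2, Slco5a1, Slx4ip and Tmem150c had 6 each, and Cmah, which hydroxylates sialic acid, and Il1rn had 5 each. None of these 15 genes had a control-specific region, which says little because such regions were only 0.244% of the merged set. A one-sided binomial test of each gene's regions against the overall share of 3.50%, chosen after the regions were seen and adjusted by Benjamini-Hochberg over 16380 genes, called 12 genes. Adjusted p was 0.00382 for Slc7a11 and for Pakap, 0.0105 for Ptpn14, 0.0192 for Il1rn and for Slco5a1 and 0.0203 for Atxn1. Arnt2, Ralgapa2, Slx4ip and Tmem150c had 0.0325 each. The other called genes were Oprd1 (4 of 4 merged regions, 0.00819) and Mmp20 (4 of 6, 0.0325), named after their values were seen. Runx2 did not pass (8 of 41, 0.0966), nor did Rad51b (0.621), Eea1 (0.511), Phlpp1 (0.904) or Cmah (0.632). The test treats neighbouring regions as independent, but 8.53% of the Carm1-KO-specific regions without a control peak lay within 20 kb of one with a control peak, against a mean of 4.02% for merged regions with like surroundings. The p-values per gene take no account of such clustering. Nor do they account for position, because Carm1-KO-specific regions were less frequent near gene ends. For a gene whose regions lie mostly away from gene ends, the overall share of 3.50% is therefore a low base. Calls near the threshold may depend on this.

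Slc7a11 spans 50364936 to 50499087 on chromosome 3. In the gene and the 100 kb on either side, the Carm1-KO list held 59 peaks and the control list 30. The 9 Carm1-KO-specific regions ran from 50307453 to 50576144, and 5 of them overlapped no control peak. The strongest of the 9, at 50575955 to 50576144, lay 77.0 kb beyond the gene and had a fold of 33.2 in the Carm1-KO list.

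**Figure D3:**
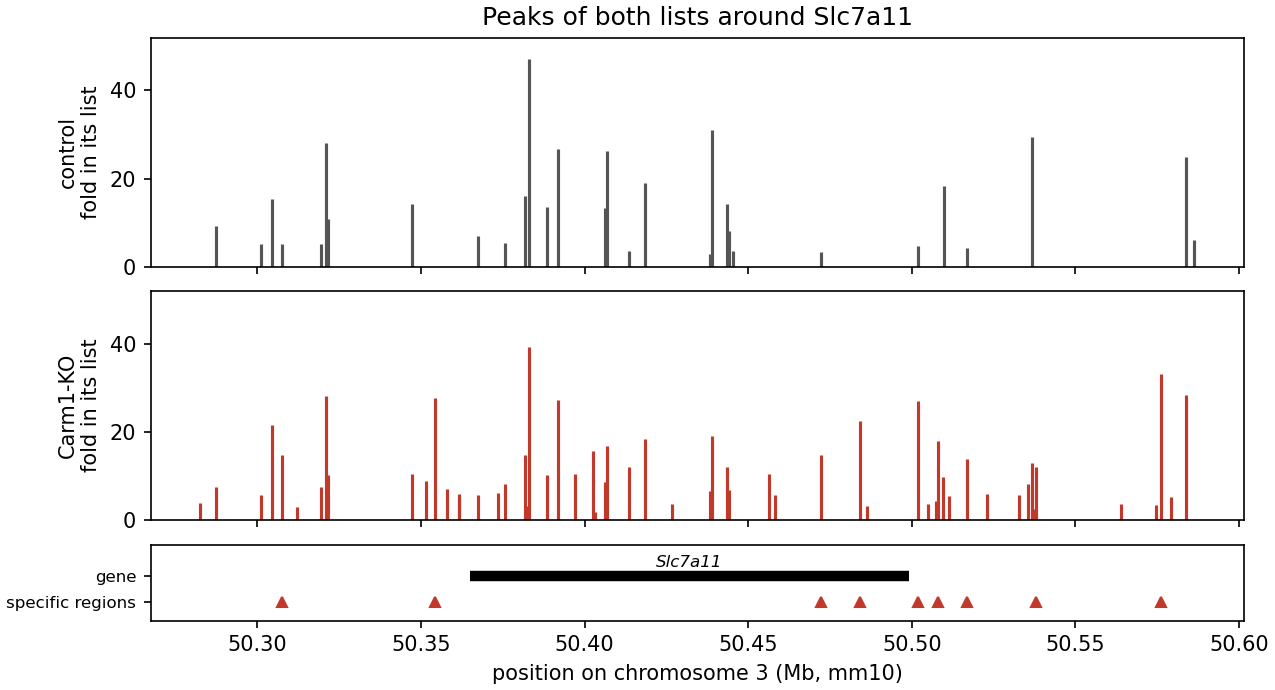
Peaks of the control (grey) and Carm1-KO (red) lists around Slc7a11 on chromosome 3, drawn at their mid-points with the authors' fold enrichment in their own list as height, above the gene (bar) and the Carm1-KO-specific regions (triangles). The window holds 30 control and 59 Carm1-KO peaks and 9 specific regions.

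The 5 Carm1-KO-specific regions with the highest fold in the Carm1-KO list were single sites. They lay inside Ift80 (chromosome 3, 68927746 to 68927935, fold 54.9), 0.464 kb from Togaram1 (chromosome 12, 65022942 to 65023131, 51.6), 25.4 kb from Atg4c (chromosome 4, 99163652 to 99163841, 51.2), inside Mrpl45 (chromosome 11, 97322055 to 97322244, 50.8) and 78.5 kb from Cited2 (chromosome 10, 17644594 to 17644783, 50.1). Only the Atg4c region among these 5 overlapped a control peak, of fold 4.95 in the control list.

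None of the 20 lists fixed before the data were examined held more genes with a Carm1-KO-specific region than matched gene sets after adjustment. The lists with the lowest adjusted p were innate sensing, with 10 of 34 genes against 5.45 expected (permutation test, one-sided p = 0.0264, adjusted p = 0.349), dendritic cell maturation, costimulation and migration, with 12 of 31 against 7.46 (p = 0.0384, adjusted p = 0.349), and stem and progenitor markers, with 7 of 16 against 3.93 (p = 0.0524, adjusted p = 0.349). Innate sensing included the receptor genes Tlr6 and Tlr1, with regions 0.704 and 0.832 kb inside a gene end, Sting1 (1.55 kb inside) and Ikbke (0.717 kb outside the gene). Tlr6 had a fold of 32.7 in the Carm1-KO list and 4.52 in the control list at this region, and the regions named for Tlr1, Ikbke and Sting1 overlapped no control peak, while 1 of the other Tlr1 regions did (fold 7.32 in the control list). The maturation list included Slco5a1, Cd200 (3 regions), Fscn1, which bundles actin, and Cd274, the gene of PD-L1, whose region lay 4.5 kb inside the gene. With genes assigned only up to 20 kb, the maturation list passed (ratio to expected 2.27, permutation adjusted p = 0.0422).

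Lists of antigen presentation, interferon response, cytokine and cDC1 identity genes did not pass. The list of antigen processing for MHC class I and cross-presentation had 4 genes against 3.39 expected (permutation adjusted p = 0.818): Tap2, the peptide transporter subunit, at 2.58 kb, Nlrc5, the transactivator of MHC class I genes, at 5.73 kb, Sec61b at 8.09 kb and Rab11a at 29.1 kb. MHC class II presentation had 1 gene, Ctss, against 1.66 (0.958). The type I interferon response had 6 genes against 5.35 (0.818), among them Ifnar1 at 1.12 kb, Ifi211, Ifi207 and Oas2. The interferon gamma response had 7 against 4.37 (ratio 1.60, 0.459), and its nearest members were the guanylate-binding protein genes Gbp7, Gbp8, Gbp10 and Gbp4, at 0.226, 0.228, 0.276 and 2.06 kb. Cytokines and chemokines had 6 against 4.62 (0.762), among them Il12a and Il12b, which encode both chains of interleukin 12, at 6.81 and 9.79 kb, Il27 at 1.06 kb and Ccl22 at 11 kb. The cDC1 identity list had 6 against 5.94 (0.855), including Tlr3 at 6.35 kb, Zfp366, Flt3 and Btla.

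Lists of other cell functions did not pass either. CARM1 substrates and coactivators had 1 gene, Ep300, against 4.77 expected, below the central 95% of matched sets (2 to 8), a direction that the one-sided test did not cover (upper-tail permutation adjusted p = 1). It lay inside its range with no distance limit (3 against 5.22, 2 to 9) and by nearest gene end (1 against 4.2, 1 to 8). The same held at regions with a control peak (1 against 2.42, 0 to 5). The count lay below its range up to 20 kb (0 against 3.77, 1 to 7), matched on peaks of either list (1 against 4.79, 2 to 8) and at regions with no control peak (0 against 3.17, 1 to 6). Matching did not cover distance from gene ends, near which Carm1-KO-specific regions were less frequent. Over 20 lists, a count outside its central 95% can also arise by chance. No conclusion is drawn from this low count. Protein arginine methyltransferases had 0 against 0.640 (1). Glycolysis had 4 against 3.62 (0.849), with Slc2a1, Hk2, Pfkfb3 and Pdk1, and cell cycle had 7 against 4.58 (0.459), with Cdk1, Mki67, Cdkn1b and Ccnd3 nearest.

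Marker genes of the other cells that a marrow culture could hold gave cDC2 markers 8 genes against 4.87 expected (permutation adjusted p = 0.367), with Rbpj, Esam, Epcam and Sirpa nearest, and stem and progenitor markers 7 against 3.93 (0.349), with Slamf1, Gfi1b, Kit and Sox4. Plasmacytoid DC markers had 4 against 4.10 (0.862), namely Runx2, Blnk, Tcf4 and Bcl11a. Monocyte and macrophage markers had 3 against 3.91 (0.928), namely C1qb, Trem2 and Mertk. Neutrophil and granulocyte precursor markers had S100a9 and Gfi1 (2 against 1.41, 0.818), B cell markers Cd22, Cr2 and Blnk (3 against 1.59, 0.552), T and NK cell markers Il7r and Tcf7 (2 against 1.92, 0.855), and mast cell, basophil and erythroid markers Tpsb2 (1 against 1.02, 0.862). Fisher's exact test on genes without matching on their number of regions called 4 lists: maturation (adjusted p = 0.0047), cDC2 markers (0.0142), stem and progenitor markers (0.0142) and innate sensing (0.0393).

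**Figure D4:**
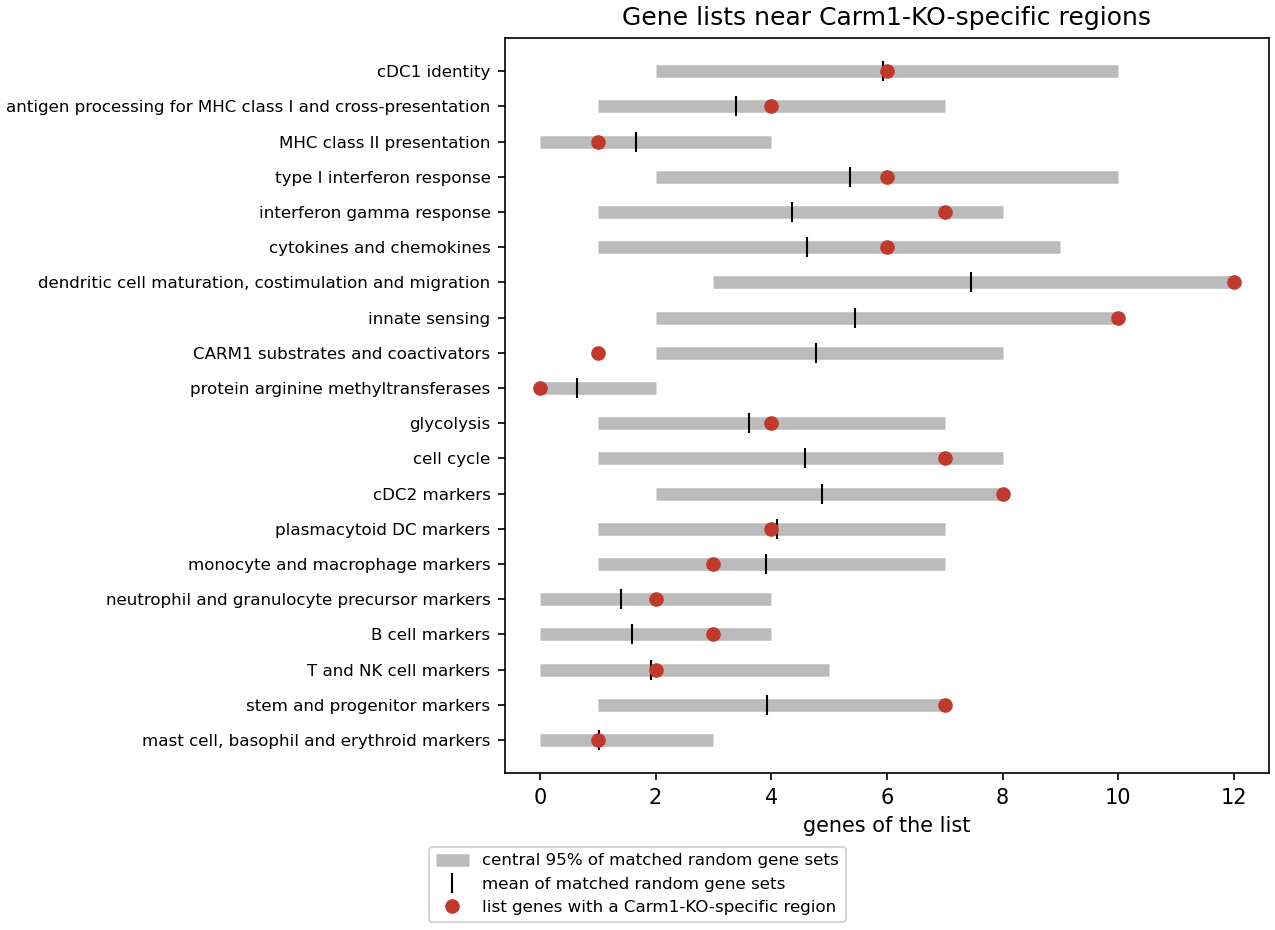
Number of genes with at least 1 Carm1-KO-specific region in each of the 20 lists (points), with the mean (ticks) and central 95% (grey bars) of random gene sets matched on the number of merged regions per gene. The maturation list had 12 genes against a mean of 7.46, and innate sensing 10 against 5.45.

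Control-specific regions were few and scattered over 180 genes within 100 kb. Ano6, a lipid scramblase gene, Cxcr3, a chemokine receptor gene on X, Fbxw7, a ubiquitin ligase subunit gene, Gm38469 and Pcdh7 had 2 each. The next genes in the order fixed beforehand, 1700011L22Rik, 2700049A03Rik, 4833420G17Rik, Abhd5 and Acmsd, had 1 each. The 5 regions with the highest fold in the control list lay inside Gpr137b (chromosome 13, 13378334 to 13378523, fold 25.7), Gm7609 (chromosome 1, 85199631 to 85199820, 22.0), Arhgap6 (chromosome X, 169051656 to 169051845, 21.1), Ttc37 (chromosome 13, 76144273 to 76144462, 21.1) and Bbs9 (chromosome 9, 22539992 to 22540181, 20.9). List members near such regions were Ifi209 (type I interferon response), Tlr13 (innate sensing), Tcf4 (plasmacytoid DC markers) and Cd14 (monocyte and macrophage markers), 1 gene each, and the other 16 lists had none. No list passed (permutation adjusted p = 1 for each), and 0 lists had an unadjusted p under 0.05. Both kinds of region were assigned to 42 genes, Fbxw7 and Gm38469 among them, against 55.0 for matched genes (one-sided permutation p = 0.994 for an excess). The count lay below the central 95% of 44 to 66, a direction that the test did not cover.

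Both kinds of region lay away from gene ends. Of the Carm1-KO-specific regions, 105 (3.36%) lay within 1 kb of an end of a protein-coding gene, against 15.6% of the other merged regions (Fisher's exact test, two-sided, odds ratio 0.187, 95% interval 0.153 to 0.228, p = 2.29e-107). Of the control-specific regions, 6 (2.75%) did, against 15.2% (Fisher's exact test, odds ratio 0.157, 0.0571 to 0.348, p = 2.12e-09). The median distance to a gene end was 24.1 kb for Carm1-KO-specific regions and 13.7 kb for the rest, and 31.5 against 14 kb for control-specific regions. Inside a gene span lay 47.5% of the Carm1-KO-specific regions and 55.2% of the rest. Regions are not replicates, so these tests describe where the listed regions lie.

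By chromosome, the Carm1-KO-specific regions were less frequent on X (54 regions, 1.73% against 2.54% of the rest, odds ratio 0.675) and on chromosome 7 (147 regions, 4.70% against 6.02%, odds ratio 0.770), each with a Fisher's exact adjusted p of 0.0372. With regions less than 10 kb apart taken as 1 locus, X passed (Fisher's exact adjusted p = 0.001) and chromosome 7 did not (0.417). Control-specific regions on X numbered 13 (5.96% against 2.5%, odds ratio 2.47, Fisher's exact adjusted p = 0.0775). The 10 Mb on either side of Carm1 held 0.512% of the Carm1-KO-specific regions and 0.602% of the rest (Fisher's exact adjusted p = 0.742).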

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

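All thresholds for strong peaks without a counterpart and the restrictions of the gene lists by control peak were chosen after seeing the data. The share of control peaks overlapped was 75.8% with 50% reciprocal overlap, 79.3% with summits at most 100 bp apart, 83.2% and 84.2% at a −log10 q of at least 5 and 10, and 85.6% among the 30000 strongest peaks. For Carm1-KO peaks these shares were 75.2%, 78.7%, 85.0%, 86.8% and 86.0%. Strong peaks without a counterpart numbered 4244 Carm1-KO and 198 control at a −log10 q of at least 30, and 1183 and 1 at 100. With no peak within 500 bp, 2032 Carm1-KO and 8 control peaks remained. Only 1863 Carm1-KO-specific and 1 control-specific regions had a peak of their group and none of the other. The odds ratios at gene ends stayed below 1 and past the threshold under every alternative run, including a background matched on width and fold (0.238, p = 2e-05, the smallest the permutations can give, and 0.258, p = 4e-05). The number of lists called near Carm1-KO-specific regions, 0 as reported (2 with an unadjusted p under 0.05), became 1 up to 20 kb, 4 by Fisher's exact test on genes and 3 by Fisher's exact test on regions. Both Fisher tests leave out the matching. For the 4 lists called on genes, matching lowered the ratio to expected at the same number of genes. It fell from 3.05 to 1.61 (maturation), 3.15 to 1.64 (cDC2 markers), 3.44 to 1.78 (stem and progenitor markers) and 2.31 to 1.83 (innate sensing). The test on regions called cDC2 markers (Fisher's exact adjusted p = 0.000572), maturation (0.00178) and stem and progenitor markers (0.0428). That test treats regions of the same gene as independent. The 19 cDC2 regions came from 8 genes, the 23 maturation regions from 12 and the 12 stem and progenitor regions from 7. The cause of the calls on regions was not tested. Chromosomes that differed for Carm1-KO-specific regions fell from 2 to 1 by locus, and the cause was not tested. No paired analysis was possible because the pooled lists carry no replicate numbers, and leaving out a replicate was not possible for the same reason. The motif alternatives were not run. Depth limits what the absence of a weak peak shows.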

Other observations

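The tests of strong peaks, maturation genes and chromosome X, the exact sum for gene families and the split of their first stem were chosen only after the result was seen. The family test itself was set before it was run.

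Gene families that share a symbol stem gave a further view of the Carm1-KO-specific regions. Of 281 families with at least 8 genes, the stem St ranked first, with 13 of 23 genes against 5.54 expected. Of the 18 sialyltransferase genes under that stem, 10 had a region: St3gal1, St3gal2, St3gal3, St3gal5, St6gal1, St6galnac3, St6galnac5, St6galnac6, St8sia4 and St8sia6 (4.6 expected). The other 3, St14, St18 and St7, are unrelated genes that share the letters, and they were 3 of 5 such genes against 0.939 expected. For the whole stem, the adjusted p was 0.0421 by 100000 random draws and 0.0503 when summed exactly, so the draws' call came from sampling error. The sialyltransferases alone had an unadjusted permutation p of 0.00248, against an exact unadjusted p of 0.000179 for the stem with its unrelated genes. The value near the threshold is thus that of the stem. The stem held only 13 of the 2082 genes with a Carm1-KO-specific region, so it does not gather most of them. Whether a single family holds more such genes than matched sets stays open. The next families were Bcl, with 11 of 23 genes, among them Bcl2, Bcl6 and Bcl2l11 (4.90 expected, exact adjusted p = 0.124), and Il, with 19 of 68, among them Il6, Il2ra and Il1r1 (10.1 expected, 0.208).

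The control list had 16 strong peaks with no counterpart, and the Carm1-KO list had 2605, spread over 20 chromosomes. Deeper sequencing of the Carm1-KO pool, at like enrichment over background, would give it more strong peaks. But it had 0.951 times as many as the control list at a −log10 q of at least 50. Depth and enrichment are unknown for each pool, so this argues only against greater depth at like enrichment. A strain segment or copy number change over a whole chromosome or the Carm1 flank would gather the regions there. But over 20 chromosomes and this flank the highest odds ratio of regions without a control peak was 1.28 (chromosome 1, Fisher's exact adjusted p = 0.039). X had 0.565 with the same adjusted p. Shares of whole chromosomes cannot show a smaller segment elsewhere, and strain differences scattered over the genome were not tested. If all 1863 were scattered false peaks, they would ignore other regions. But 8.53% of them lay within 20 kb of a Carm1-KO-specific region that has a control peak. In 1000 draws of merged regions with like surroundings, this share was at most 5.69%. This argues only against the case that all are scattered, because most of the 1863 had no such neighbour. The cells were sorted, by a gate not given in the sources used here, but cells of another type in the Carm1-KO pool cannot be told apart from a change within cDC1s (lowest adjusted p of the 8 marker lists 0.452, for stem and progenitor markers, 6 genes against 2.57 expected, unadjusted p = 0.0226, permutation test), nor can an origin in 1 of the 4 libraries, and loss of Carm1 stays open as the biological explanation.

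Maturation genes took 14 of the 1264 Carm1-KO-specific regions with a control peak (1.11%) and 9 of the 1863 without (0.483%). A chance split stays possible (Fisher's exact p = 0.0547, adjusted p = 0.44 over all lists), and that test treats regions of the same gene as independent. Maturation did not have the lowest p by this test. Antigen processing for MHC class I and cross-presentation had 5 regions with a control peak and 0 without (Fisher's exact p = 0.0107, adjusted p = 0.214). No list passed this test after adjustment. Counted by gene, the maturation list had 7 genes at regions without a control peak against 4.89 expected (permutation adjusted p = 0.987). A hypothesis is that the Carm1-KO pool held more mature cDC1s, whose sites may be open in fewer control cells. At regions with a control peak the list had 8 genes against 3.53 expected (permutation adjusted p = 0.123), but this count reuses the regions that raised the hypothesis, which therefore stays untested. At the same regions innate sensing had 7 against 2.55 and cDC2 markers, of another cell type, 6 against 2.35, each with the same adjusted p.

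The lower share of Carm1-KO-specific regions on X might come from different sex of the animals of the groups. Against this, both lists held 0 peaks on Y below 90 Mb, and their first Y peaks stood at 90738828 and 90737845, near the end shared with X. No biological explanation of the X share was tested.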
